A study of Mus musculus with 6 samples.

How the data were processed

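RNA from 6 libraries labelled MIN6 was sequenced, 3 labelled control and 3 labelled PP2Ac knockdown. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. The authors deposited 1 table of FPKM values, read numbers scaled for gene length and library depth, for 54532 Ensembl genes with name, position, strand, length and biotype. Per the submitters' processing notes the genome builds are GRCm38 and mm10; the aligner, the counter and the strand setting are not given in the sources used here, so reads of overlapping, antisense and near-identical genes may have been split or lost. In the reference annotation used here, GENCODE M21, 99.9% of the gene identifiers occur and 98.3% have the same start, end and strand.

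FPKM times the gene length was a whole multiple of one step for 100% of non-zero values in each library, within 0.01 of a whole number, which gave the reads per gene. Recovered reads came to 14614737 to 16030939 per library. The library total implied by the step differed from these sums by -1.53% to 2.42%. A gene with no read was set against the level of 3 reads in each library, which covers counting error only. Replicates of a group correlated at 0.986 to 0.989 across genes on the log2 scale, and libraries of different groups at 0.911 to 0.934; genes are not independent replicates. Within groups the reads differed beyond sampling noise, with chi-square per degree of freedom of 6.58 to 10.0, so none were merged as copies of one library; this check cannot show that they came from separate cultures.

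The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are knockdown minus control on that scale, which understates the change of low genes. A count test was planned only for a table of counts and was not run. Ppp2ca was also tested by a two-sided exact permutation test, for which 3 against 3 libraries cannot go below 0.1. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

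Before the data were examined, 33 gene lists were fixed from textbook knowledge, covering PP2A, beta cell function, stress, apoptosis, metabolism, signalling, inflammation, protein turnover, matrix and markers of other cells. The 30 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation and with fry. A symbol that names more than 1 gene in the table was counted once per gene. Members were counted as higher, lower or not past the threshold over all genes and adjusted over the list alone. The named genes follow a rule fixed at the same time: genes always named (among them Ppp2ca, Ppp2cb, Ins1, Ins2, Pdx1, Mafa, Nkx6-1, Slc2a2, Bcl2, Bax and Ddit3), the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap and whose higher group had a mean FPKM of at least 5, without predicted genes, pseudogenes and non-coding RNA, and up to 4 members per list with the smallest p. Some genes that the rule names are not reported here.

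In data simulated for this comparison, 200 chosen genes were given known changes and the cholesterol synthesis list was shifted by 1.3-fold, and 11669 genes passed the filter and were tested. Of the chosen genes that passed the filter, limma recovered 52.3% of 65 changed by 1.5-fold, 93.8% of 65 at 2-fold and 98.4% of 63 at 4-fold. In this simulation 8% of the calls were false, and none was made when no change was simulated. All genes were simulated independently with a single dispersion of 0.01. A far smaller share of genes was changed than the 62.4% called in the data, so these rates may not hold there. Alternatives fixed beforehand were other pseudocounts, filters, scalings, variance models, array weights, protein-coding genes only, a replicate block and leaving out each library. Those added after seeing the data were limma voom on the recovered reads, and removal of mitochondrially encoded genes, rRNA and Gm23935. After this removal, and with protein-coding genes only, each library was rescaled to its own original FPKM sum. The original sums differed between libraries, from 327005 to 376056. That rescaling acts on sums of FPKM, in which the short Gm23935 weighs more than in reads.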

Results

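Gene expression was measured by RNA sequencing in 6 mouse libraries labelled MIN6, an insulinoma-derived pancreatic beta cell line. The labels assign 3 libraries to a control group and 3 to knockdown of PP2Ac, the catalytic subunit of protein phosphatase 2A, a major serine/threonine phosphatase. The values were FPKM for 54532 genes, from which 14614737 to 16030939 reads per library were recovered. The title of the series concerns lipid-induced damage to beta cells, and the labels name no lipid treatment for these libraries. The comparison therefore asks which transcripts differ between PP2Ac knockdown and control cells.

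Transcripts that define beta cells were at or near 0 in both groups. Ins1 and Ins2, which encode insulin, were listed at 0 in all 6 libraries, as were Nkx6-1, a beta cell transcription factor, and Slc2a2, a glucose transporter. At this depth 3 reads would have given an FPKM of at most 0.202 for Ins1 and 0.156 for Ins2. Of 38 beta cell identity genes in the table, 30 had a mean FPKM below 1 and 15 were at 0 in every library. By contrast, Vim, an intermediate filament gene of mesenchymal cells, had a mean FPKM of 426 in control, Spp1, which encodes osteopontin, 760, and Fn1, which encodes fibronectin, 130. These 3 genes were chosen after their values were seen, and Spp1 was on the fixed list of duct cell markers. Other matrix genes were low in control, such as Col3a1 (0.834) and Col6a2 (0.0198), although 37 of 47 matrix and adhesion genes had a mean FPKM of at least 1 over the 6 libraries. Of 20 stromal, endothelial and immune markers, 15 were below 1. The libraries are therefore named below by their labels, without the assumption that they hold typical beta cell RNA.

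**Figure D1:**
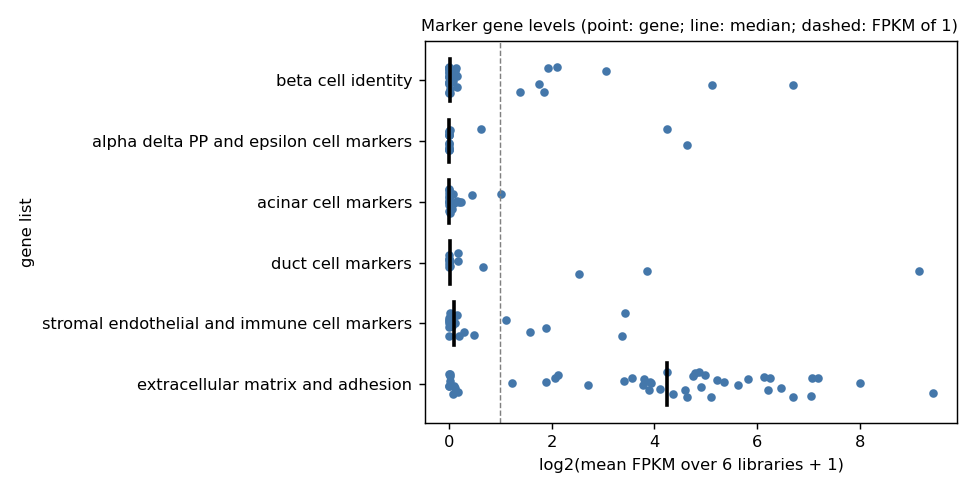
Mean FPKM over the 6 libraries on a log2(FPKM + 1) scale (x axis) for each gene of 6 marker lists (y axis); points are genes, black lines are medians and the dashed line marks an FPKM of 1. Of the 38 beta cell identity genes, 30 lie below an FPKM of 1, whereas 37 of 47 extracellular matrix and adhesion genes had a mean FPKM of at least 1.

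The targeted transcript was lower in every knockdown library. Ppp2ca (ENSMUSG00000020349, chromosome 11, 52098681 to 52127778, plus strand, GRCm38), which encodes the alpha isoform of the PP2A catalytic subunit, had 42.5, 34.6 and 35.6 FPKM in the control libraries and 10.1, 11.4 and 10.9 FPKM in the knockdown libraries. The means were 37.6 ± 4.33 (SD, n = 3) and 10.8 ± 0.617 (SD, n = 3), so 28.7% of the control level was left. Its log2 fold change was -1.70 (SE 0.0917, limma adjusted p = 5.35e-06). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Ppp2cb (ENSMUSG00000009630, chromosome 8, 33599625 to 33619441, plus strand), which encodes the beta isoform, averaged 101 ± 10.6 FPKM in control and 86.9 ± 3.45 FPKM in knockdown (SD, n = 3), a log2 difference of -0.21 that did not pass the threshold (limma adjusted p = 0.066). It did pass under 7 alternative settings, named in the closing section. The summed FPKM of both genes was 139 ± 14.4 in control and 97.7 ± 4.01 in knockdown, or 70.5% of control. This sum depends on the gene lengths used for FPKM. In recovered reads Ppp2ca was the larger in control, with 5095, 4017 and 4377 reads against 2630, 2287 and 2189 for Ppp2cb. In knockdown Ppp2ca had 1174, 1303 and 1218 reads and Ppp2cb 1884, 1997 and 1954. The share of PP2Ac transcript left is therefore uncertain.

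**Figure D2:**
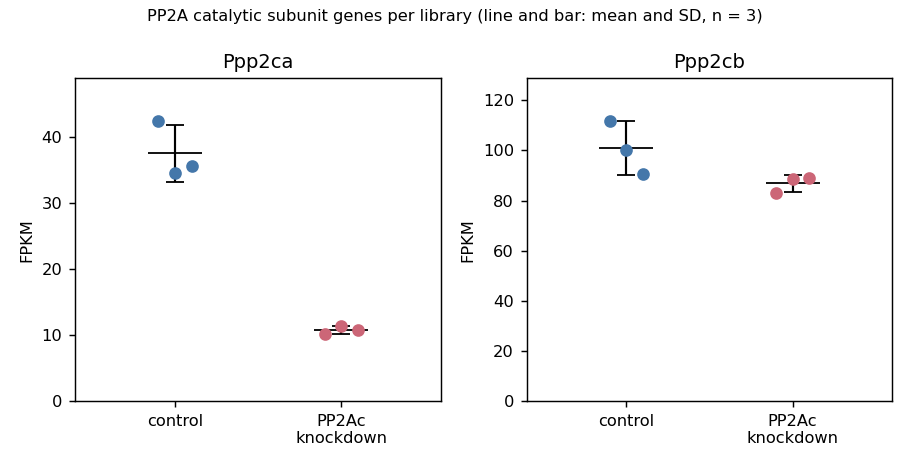
FPKM of Ppp2ca and Ppp2cb (y axes, starting at 0) in the control and PP2Ac knockdown groups (x axes); points are libraries, horizontal lines means and bars SD (n = 3). The knockdown libraries lie between 10.1 and 11.4 FPKM for Ppp2ca, all below the control libraries at 34.6 to 42.5.

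Expression differed widely between the groups. Ptk7, which encodes a Wnt pathway pseudokinase, rose from 0.248 ± 0.0271 to 22.9 ± 2.18 FPKM, and the collagen gene Col3a1 rose from 0.834 ± 0.304 to 31.7 ± 4.58 FPKM (SD, n = 3). Avil, which encodes the actin regulator advillin, fell from 54.2 ± 6.07 to 0.906 ± 0.169 FPKM, and Car6, a secreted carbonic anhydrase gene, fell from 138 ± 16.4 to 5.58 ± 0.0635 FPKM. Of 11652 genes tested, 7267 (62.4%) passed a limma adjusted p of 0.05, with 3879 higher and 3388 lower in knockdown. Among these, 588 were higher and 561 lower by at least 1 on the log2 scale, 1149 in all; this count moved to 1749 and 1814 with pseudocounts of 0.1 and 0.01, to 1792 with voom (853 higher, 939 lower) and to 700 with a mean FPKM of at least 5. In 68.1% of tested genes the 2 groups did not overlap, against 10% by chance for 3 against 3. Counts of changed members in each list below are to be read against the 62.4% of all tested genes that changed. In 1 alternative, mitochondrially encoded genes, rRNA and Gm23935 were removed and each library was rescaled to its own original FPKM sum. Those sums averaged 362139 in control and 341439 in knockdown, so the libraries were not set equal. With this removal 2816 genes were higher and 4356 lower. By at least 1 on the log2 scale, 432 were then higher and 797 lower. The median log2 change of all genes moved from 0.03 to -0.11. This alternative was added after the data were seen. Of the alternatives fixed beforehand, 3 also gave more lower than higher genes. Protein-coding genes only, rescaled in the same way, gave 3158 higher and 3556 lower. The others were no filter on low values (4001 higher, 4122 lower) and median-of-ratios scaling (3607 higher, 3639 lower). No source says that the replicates came from separate cultures. The p-values therefore set each group difference only against the spread between these samples, which may not be the spread between cultures.

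The other large rises included Col6a1 (1.83 to 25.9 FPKM), Zbp1 (1.88 to 25.5), which encodes a nucleic acid sensor, Tusc1 (0.183 to 9.18), Fbxo2 (0.975 to 15.7), Mrc2 (0.525 to 11.9), a collagen receptor gene, Apcdd1 (0.816 to 13.9), a Wnt inhibitor gene, Col1a1 (9.95 to 86.9) and Atoh8 (0.601 to 11.7). The other large falls included Sh2d6 (24.9 to 0.604 FPKM), Mamdc2 (10.6 to 0.0857), Ndrg1 (129 to 16.2), a hypoxia-responsive gene, Prkg2 (38.2 to 4.53), Gadd45a (109 to 15.0), a stress-responsive growth arrest gene, Pla2g2e (28.1 to 3.30), Cox6a2 (20.7 to 2.38) and Atp2a3 (12.7 to 1.25), which encodes an endoplasmic reticulum calcium pump. The rule that chose these genes required the 3 knockdown libraries to lie on one side of the 3 control libraries, so this separation adds no support. Their limma adjusted p values ran from 7.95e-08 for Sh2d6 to 1.25e-05 for Cox6a2.

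**Figure D3:**
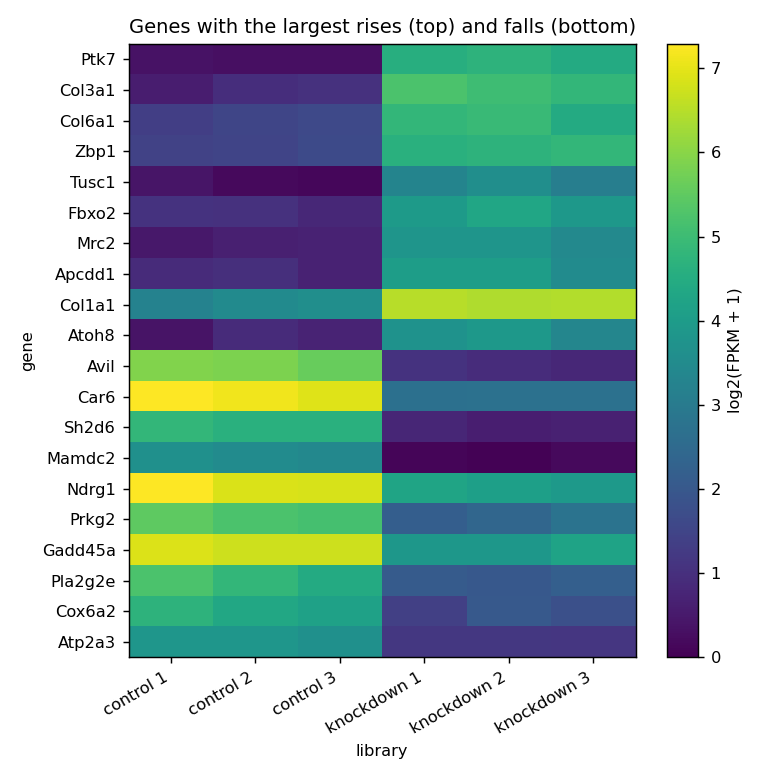
Expression on a log2(FPKM + 1) scale (color) of the 10 genes with the largest rises (top) and the 10 with the largest falls (bottom) in each of the 6 libraries (columns). These genes were chosen among those whose groups did not overlap, and Avil goes from a mean of 54.2 FPKM in control to 0.906 FPKM in knockdown.

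Interferon-stimulated genes rose as a group. Of 44 tested members, 37 were higher, 2 lower and 5 did not pass; 40 changed when adjusted over the list alone. The median log2 change was 1.21, with camera adjusted p = 1.32e-11 and adjusted p = 0.349 with an estimated correlation. Zbp1 rose as given above, Irf7, a transcription factor of the interferon response, rose from 29.5 ± 1.13 to 130 ± 10.5 FPKM, Cmpk2 from 1.21 ± 0.0572 to 9.41 ± 0.862 FPKM and Oas3, which senses double-stranded RNA, from 13.4 ± 0.836 to 44.3 ± 0.827 FPKM.

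Genes of the ATF4 and amino acid response fell together. None of 31 tested members was higher, 28 were lower and 3 did not pass, and 28 changed when adjusted over the list alone. Their median log2 change was -0.78, with camera adjusted p = 2.77e-10 and adjusted p = 0.349 with an estimated correlation. Ddit3, which encodes the stress-induced transcription factor CHOP, fell from 97.1 ± 3.32 to 28.6 ± 2.07 FPKM, and Trib3 from 227 ± 10.2 to 76.1 ± 2.37 FPKM. Aldh1l2, a mitochondrial folate enzyme gene, fell from 58.0 ± 3.67 to 20.2 ± 0.803 FPKM, and Cebpg from 24.9 ± 1.57 to 10.5 ± 0.493 FPKM. The unfolded protein response list was divided, with 17 of 30 members higher, 10 lower and 3 not past the threshold, 27 changed when adjusted over the list alone, camera adjusted p = 0.573 and adjusted p = 0.733 with an estimated correlation. In it, Ppp1r15a, which encodes a phosphatase subunit acting on eIF2 alpha, fell from 150 ± 25.8 to 26.2 ± 2.79 FPKM and Atf6 from 38.2 ± 3.35 to 12.5 ± 0.706 FPKM, while Pdia4, a protein folding enzyme gene, rose from 47.1 ± 2.63 to 117 ± 4.80 FPKM.

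Lipid synthesis genes rose. For cholesterol synthesis, 23 of 24 tested members were higher and 1 lower, and 24 changed when adjusted over the list alone; the median was 0.90, camera adjusted p = 8.41e-08 and adjusted p = 0.579 with an estimated correlation. Acat2 rose from 14.9 ± 0.927 to 46.0 ± 3.47 FPKM, Cyp51 from 29.7 ± 1.32 to 73.4 ± 3.32, Mvd from 13.6 ± 1.56 to 35.8 ± 1.31 and Mvk from 8.01 ± 1.21 to 26.3 ± 2.09. The fatty acid and triglyceride synthesis list had 18 of 24 members higher, 1 lower and 5 not past the threshold, and 20 changed when adjusted over the list alone. Its median was 0.53, with camera adjusted p = 3.71e-05 and adjusted p = 0.627 with an estimated correlation. Fads2, a fatty acid desaturase gene, rose from 45.0 ± 6.95 to 171 ± 17.5 FPKM, Fasn, which encodes fatty acid synthase, from 30.3 ± 2.39 to 78.5 ± 6.12, and Slc25a1, the mitochondrial citrate carrier gene, from 26.0 ± 0.966 to 72.1 ± 9.10. Fatty acid oxidation and PPAR target genes went both ways, with 10 of 33 higher, 11 lower and 12 not past the threshold, 21 changed when adjusted over the list alone, camera adjusted p = 0.955 and adjusted p = 0.984 with an estimated correlation. For that list the median (0.09) and the mean (0.02) were positive while camera's direction was down. Plin2, a lipid droplet coat gene, fell from 146 ± 27.0 to 45.8 ± 3.28 FPKM, and Ucp2, a mitochondrial carrier gene, rose from 1.65 ± 0.181 to 6.82 ± 0.696 FPKM.

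Mitochondrially encoded mRNAs fell, and nuclear genes for oxidative phosphorylation mostly did not pass the threshold. All 13 mitochondrial mRNAs were lower, 13 when adjusted over the list alone, with a median of -1.46, camera adjusted p = 3.45e-06 and adjusted p = 0.627 with an estimated correlation. Examples were mt-Nd4 (1218 ± 141 to 343 ± 8.23 FPKM), mt-Nd5 (1147 ± 113 to 369 ± 38.1), mt-Nd6 (878 ± 122 to 243 ± 29.5) and mt-Cytb (4627 ± 520 to 1718 ± 84.1). These mRNAs took 3.03% ± 0.370 of reads in control and 1.29% ± 0.059 in knockdown, and rRNA with Gm23935 took 0.702% ± 0.0811 and 0.349% ± 0.172 (SD, n = 3). Genes with at least 1 read numbered 21572 ± 138 in control and 19768 ± 200.4 in knockdown (SD, n = 3), and 166 small nuclear and nucleolar RNA genes had a median log2 change of -0.61, with 61 lower, 5 higher and 100 not past the threshold. Of 60 nuclear oxidative phosphorylation genes, 14 were higher, 6 lower and 40 not past the threshold, and 17 changed when adjusted over the list alone; camera adjusted p was 0.688, and adjusted p = 0.984 with an estimated correlation. Ndufb8, a complex I gene, rose from 12.8 ± 1.54 to 25.8 ± 2.32 FPKM, and Ndufs1, another, fell from 14.8 ± 1.58 to 10.1 ± 0.600 FPKM.

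Extracellular matrix and adhesion genes rose, with 24 of 37 tested members higher, 5 lower and 8 not past the threshold, and 30 changed when adjusted over the list alone. The median was 0.60, camera adjusted p = 7.43e-05 and adjusted p = 0.627 with an estimated correlation. Besides Col1a1 and Col3a1, Col6a1 rose from 1.83 ± 0.246 to 25.9 ± 4.35 FPKM and Col6a2 from 0.0198 ± 0.0150 to 5.34 ± 0.777 FPKM. Among 5 tested stromal, endothelial and immune markers, 4 were higher and 1 lower, 5 changed when adjusted over the list alone, camera adjusted p was 0.399, and adjusted p = 0.733 with an estimated correlation: Pdgfrb, a stromal growth factor receptor gene, rose from 6.81 ± 0.579 to 12.6 ± 1.58 FPKM, Pdgfra from 0.734 ± 0.0418 to 1.58 ± 0.0974 and Eng from 1.16 ± 0.162 to 2.84 ± 0.0515, while Cd68, a macrophage and lysosomal gene, fell from 16.5 ± 3.82 to 2.27 ± 0.310.

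Antioxidant genes and NRF2 targets rose, with 22 of 37 higher, 4 lower and 11 not past the threshold, and 26 changed when adjusted over the list alone. The median was 0.43, camera adjusted p = 0.000616 and adjusted p = 0.627 with an estimated correlation. Srxn1, which encodes sulfiredoxin, rose from 28.5 ± 2.83 to 82.4 ± 2.54 FPKM, Gsta4, a glutathione transferase gene, from 5.37 ± 0.368 to 27.1 ± 4.47, Pgd from 42.2 ± 3.77 to 94.0 ± 5.002 and Prdx2, a peroxiredoxin gene, from 42.1 ± 3.78 to 99.5 ± 7.74. Cytosolic ribosomal protein genes were lower as a list, with 7 of 78 higher, 25 lower and 46 not past the threshold, and 27 changed when adjusted over the list alone. Their median was -0.16, camera adjusted p = 0.0258 and adjusted p = 0.733 with an estimated correlation. This call was lost without control library 2, without knockdown library 1 or 3, with no filter on low values, and with fry (adjusted p = 0.110). Rpl34 fell from 324 ± 13.7 to 196 ± 7.03 FPKM and Rpl5 from 250 ± 20.5 to 167 ± 3.24 FPKM. Many genes of this family have near-identical pseudogenes, so their values are uncertain.

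**Figure D4:**
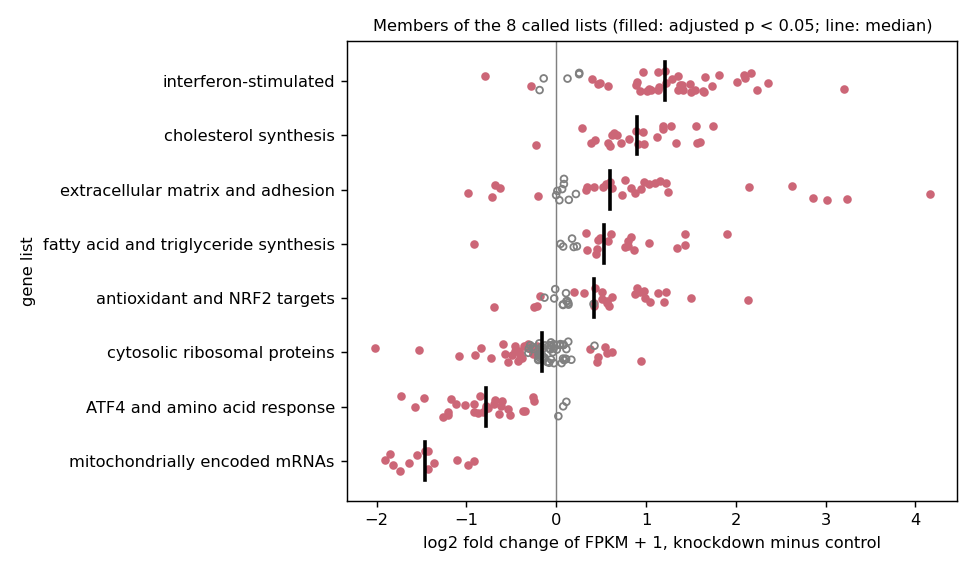
Log2 fold change of FPKM + 1, knockdown minus control (x axis), for each tested member of the 8 lists that camera called (y axis); filled points passed an adjusted p of 0.05, open points did not, and black lines are medians. Medians run from -1.46 for mitochondrially encoded mRNAs to 1.21 for interferon-stimulated genes.

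Apoptosis genes moved in part, and camera called neither apoptosis list. Over all tested genes 62.4% changed, so the counts of changed members are to be read against that share. Of 29 pro-apoptotic genes tested, 16 were higher, 4 lower and 9 not past the threshold, and 20 changed when adjusted over the list alone, with camera adjusted p = 0.236 and adjusted p = 0.627 with an estimated correlation. Bok rose from 20.2 ± 1.06 to 40.5 ± 1.86 FPKM, Bak1, a pore-forming BCL2 family gene, from 38.1 ± 2.74 to 60.9 ± 3.72 and Casp8 from 5.81 ± 0.267 to 8.75 ± 0.239. Bax rose from 140 ± 7.09 to 167.0 ± 14.05 FPKM (limma adjusted p = 0.0302), a call that several alternatives ended. Of 16 anti-apoptotic genes, 5 were higher, 6 lower and 5 not past the threshold, and 11 changed when adjusted over the list alone, with camera adjusted p = 0.688 and adjusted p = 0.850 with an estimated correlation. Bcl2 fell from 2.95 ± 0.133 to 1.94 ± 0.0586 FPKM, Cflar, a caspase 8 inhibitor gene, from 11.1 ± 1.04 to 5.08 ± 0.422 and Mcl1 from 131 ± 13.3 to 66.2 ± 4.30, while Birc5 rose from 21.2 ± 1.19 to 30.2 ± 0.658. For p53 targets 11 of 29 were higher, 10 lower and 8 not past the threshold, and 23 changed when adjusted over the list alone; camera adjusted p was 0.987, and adjusted p = 0.994 with an estimated correlation. Their median was 0.09, while the mean was -0.04 and camera's direction was down. Dglucy rose from 10.5 ± 0.618 to 31.5 ± 1.32 FPKM and Plk3 fell from 44.2 ± 6.16 to 14.9 ± 0.758 FPKM.

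Of the beta cell identity genes, 8 were high enough to test. In knockdown 5 of them were higher, 1 lower and 2 not past the threshold, 6 changed when adjusted over the list alone, camera adjusted p was 0.381, and adjusted p = 0.733 with an estimated correlation. Mafa rose from 1.78 ± 0.435 to 4.86 ± 0.854 FPKM and Pdx1 from 1.68 ± 0.499 to 3.96 ± 0.309, both encoding transcription factors that activate the insulin genes. Cpe, a prohormone processing gene, rose from 82.2 ± 8.95 to 124 ± 5.22 and Ptprn from 25.6 ± 2.13 to 41.7 ± 3.01, while Nnat fell from 3.56 ± 0.184 to 1.67 ± 0.142. Insulin exocytosis genes were higher for 8 of 15, lower for 2 and not past the threshold for 5, with 10 changed when adjusted over the list alone, camera adjusted p = 0.375 and adjusted p = 0.733 with an estimated correlation. Rab3d, a secretory vesicle GTPase gene, rose from 5.34 ± 0.143 to 12.7 ± 0.811 FPKM. The disallowed and dedifferentiation list had 10 of 18 higher, 7 lower and 1 not past the threshold, 17 changed when adjusted over the list alone, camera adjusted p = 0.955 and adjusted p = 0.984 with an estimated correlation. Its median was 0.30 and its mean -0.07. Sox9, a progenitor transcription factor gene, fell from 7.89 ± 0.053 to 1.62 ± 0.245 FPKM, and Slc16a1, a lactate transporter gene, from 67.5 ± 4.86 to 39.7 ± 3.00. Too few markers of other pancreatic cells were tested for a list test: 2 of alpha, delta, PP and epsilon cells, both higher, 1 of acinar cells, higher, and 3 of duct cells, all lower, with the same counts adjusted over the list alone.

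The lists of PP2A subunits and PP2A regulators were not called by camera. With fry, which does not compare a list with other genes, both were called (fry adjusted p = 0.0187, up, and 0.00537, down). Among 17 PP2A subunit genes, 6 were higher, 1 lower and 10 not past the threshold, 7 changed when adjusted over the list alone, camera adjusted p was 0.638, and adjusted p = 0.733 with an estimated correlation. The regulatory subunit gene Ppp2r5d rose from 45.2 ± 1.19 to 63.7 ± 2.83 FPKM, Strn4 from 20.2 ± 0.925 to 28.7 ± 1.26 and the scaffold subunit gene Ppp2r1a from 94.0 ± 2.33 to 127 ± 11.6. PP2A regulators and related phosphatases had 8 of 24 higher, 10 lower and 6 not past the threshold, 20 changed when adjusted over the list alone, camera adjusted p = 0.504 and adjusted p = 0.733 with an estimated correlation. Ptpa, which encodes a PP2A activator, rose from 39.1 ± 3.77 to 79.1 ± 7.89 FPKM, and Ppp3ca, a calcineurin catalytic subunit gene, fell from 39.1 ± 1.79 to 11.4 ± 0.719 FPKM.

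Among cell cycle genes, 22 of 49 were higher, 7 lower and 20 not past the threshold, 28 changed when adjusted over the list alone, camera adjusted p was 0.196, and adjusted p = 0.733 with an estimated correlation. Ccnd3 rose from 9.08 ± 0.632 to 18.9 ± 1.54 FPKM and Aurkb, a mitotic kinase gene, from 26.3 ± 2.93 to 46.5 ± 0.332. Of 24 NF-kB and inflammatory genes, 11 were higher, 6 lower and 7 not past the threshold, 18 changed when adjusted over the list alone, camera adjusted p was 0.399, and adjusted p = 0.733 with an estimated correlation. The chemokine gene Ccl5 rose from 1.90 ± 0.591 to 20.5 ± 2.21 FPKM and Ccl2 from 1.44 ± 0.232 to 12.6 ± 1.83, while Tnfaip2 fell from 122.6 ± 8.67 to 48.3 ± 2.04. Insulin and FoxO signalling genes were higher for 14 of 29, lower for 7 and not past the threshold for 8, with 21 changed when adjusted over the list alone, camera adjusted p = 0.688 and adjusted p = 0.857 with an estimated correlation. Akt1, a kinase gene of insulin signalling, rose from 102 ± 3.89 to 161 ± 10.9 FPKM, and Gsk3b fell from 15.9 ± 0.666 to 9.36 ± 0.126 FPKM. None of the 8 lists called by camera kept its call with an estimated correlation.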

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

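The alternatives using voom on recovered reads and those without mitochondrial genes, rRNA and Gm23935 were chosen after seeing the data. Ppp2ca stayed lower and past the threshold under every alternative run, with log2 changes from -1.87 to -1.61, and from -1.76 to -1.61 when each library was left out. The number of genes changed stayed within 1.5 times, from 5182 with a mean FPKM of at least 5 to 8123 with no filter on low values, and from 6473 to 6949 when each library was left out. The count past a log2 change of 1 moved from 1149 to 1749 and 1814 with pseudocounts of 0.1 and 0.01, to 1792 with voom, and to 700 with a mean FPKM of at least 5; fewer genes were tested in the last, and the cause of the others was not tested. The number of lists called moved from 8 to 0 with camera at an estimated correlation and to 22 with fry, which does not compare a list with other genes; leaving out each library gave 7 to 9. Of the 8 called lists, 7 kept their call in every other alternative in which they could be tested, and cytosolic ribosomal proteins in 14 of 18. Over 137 named genes tested other than Ppp2ca, 2568 of 2584 values kept direction and side of the threshold, 8 lost the call, 8 gained it and 0 reversed. Bax alone lost its call, in 8 alternatives, with no filter, median-of-ratios scaling, protein-coding genes, the removal of mitochondrial genes, or any of 4 libraries left out. Ppp2cb gained it in 7, with log2 changes of -0.26 under median-of-ratios scaling, -0.30 under quantile normalization, -0.23 with array weights, -0.31 with protein-coding genes only, -0.23 with voom, -0.37 without mitochondrial genes, rRNA and Gm23935, and -0.28 without control library 3. The replicate numbers are shared by the groups, and same-numbered libraries correlated at -0.01, 0.16 and 0.05 in their deviations. Libraries with different numbers correlated at -0.18 to 0.13. With 3 libraries per group, these values cannot decide whether same-numbered libraries were paired. With the replicate block 7363 genes changed, 7053 of them shared. The count test planned for a table of counts was not run. Depth limits genes near 0: 3 reads give up to 0.202 FPKM for Ins1.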

Other observations

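Several tests of explanations were chosen only after the result was seen. They were those of depth, other lineage, lost identity, FPKM total, residual RNA, copy number as the whole cause and zinc finger genes. The table had been looked at before any of the tests of explanations was written. In addition, the standard error in the zinc finger test and the split of residual RNA by class were added after their values were known. Genes of glycolysis and hypoxia were divided, with 17 of 30 higher, 10 lower and 3 not past the threshold, 27 changed when adjusted over the list alone, camera adjusted p = 0.399 and adjusted p = 0.733 with an estimated correlation. Vegfa, a hypoxia-induced growth factor gene, fell from 88.3 ± 5.75 to 30.1 ± 2.52 FPKM and Hk2 from 19.96 ± 1.64 to 9.20 ± 0.846, whereas the glycolytic genes Eno1 (188 to 386 FPKM) and Tpi1 (195 to 315 FPKM), chosen after their values were seen, rose. Heat shock genes were higher for 11 of 21, lower for 5 and not past the threshold for 5, with 17 changed when adjusted over the list alone, camera adjusted p = 0.399 and adjusted p = 0.733 with an estimated correlation. Hsp90ab1, a cytosolic chaperone gene, rose from 779 ± 5.05 to 1781 ± 62.0 FPKM, and Hspa9, a mitochondrial chaperone gene, fell from 659 ± 51.0 to 346 ± 10.4. Of 42 proteasome genes 20 were higher, 4 lower and 18 not past the threshold, 24 changed when adjusted over the list alone, camera adjusted p was 0.117, and adjusted p = 0.733 with an estimated correlation; Psme1, an interferon-inducible activator subunit gene, rose from 25.5 ± 1.01 to 71.1 ± 1.55.

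Autophagy and lysosome genes were lower for 22 of 45, higher for 8 and not past the threshold for 15, with 30 changed when adjusted over the list alone, camera adjusted p = 0.111 and adjusted p = 0.733 with an estimated correlation. Ctsl, a lysosomal protease gene, fell from 381 ± 26.7 to 181 ± 11.3 FPKM and Grn from 221 ± 7.25 to 130 ± 9.13. Of 32 ERK feedback and immediate early genes, 7 were higher, 10 lower and 15 not past the threshold, 17 changed when adjusted over the list alone, camera adjusted p was 0.416, and adjusted p = 0.733 with an estimated correlation; Klf4 fell from 77.2 ± 7.35 to 29.9 ± 1.85 FPKM. Of 9 Wnt targets, 4 were higher, 1 lower and 4 not past the threshold, 5 changed when adjusted over the list alone, camera adjusted p was 0.399, and adjusted p = 0.733 with an estimated correlation; Fzd7, a Wnt receptor gene, rose from 8.70 ± 0.223 to 17.6 ± 0.769 FPKM. Sphingolipid and ceramide genes were higher for 7 of 22, lower for 9 and not past the threshold for 6, with 16 changed when adjusted over the list alone, camera adjusted p = 0.573 and adjusted p = 0.857 with an estimated correlation; Asah1, an acid ceramidase gene, fell from 57.4 ± 3.91 to 31.8 ± 2.09 FPKM. Of protein-coding genes, 12 were below 0.5 FPKM in control and at least 5 in knockdown, among them Ptk7 and Tusc1, and 1, Mamdc2, was the reverse.

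Beta cell transcripts were at or near 0 in libraries labelled MIN6. Loss of reads to overlapping genes is argued against, since the median share of exon bases under another gene was 0% over 30 low beta cell identity genes, and so is too little depth, since 3 reads would give at most 0.202 FPKM for Ins1 or Ins2. The libraries may hold RNA of cells of another lineage: 30 of 38 identity genes had a mean FPKM below 1, while 37 of 47 matrix genes were at 1 or more. No lineage is shown, since markers of other cells were also mostly below 1, with 15 of 20 stromal, endothelial and immune, 19 of 20 acinar, 11 of 14 duct and 14 of 16 alpha, delta, PP and epsilon markers. Beta cells that lost their identity in culture stay open, since 1 of 8 dedifferentiation and general endocrine genes, Sox9, had a mean FPKM of at least 1, and the design gives no group that bears on this pattern.

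Mitochondrially encoded mRNAs were lower in knockdown. Another class of RNA taking up the FPKM total is argued against, because their median log2 change lay -1.52 from that of nuclear oxidative phosphorylation genes, with a spread between libraries of 0.161. A difference in poly(A) selection or residual RNA may contribute, since non-polyadenylated nuclear RNA had a median log2 change of -0.57 over 176 genes, past the bound of -0.5 set for it. By class, 61 of 166 small RNA genes were lower, 5 higher and 100 not past the threshold, and 10 histone genes, with 2 lower, 2 higher and 6 not past it, decide nothing. Mitochondrial tRNA and rRNA genes had a median log2 change of -0.60, with 8 of 18 lower, 0 higher and 10 not past the threshold. None of these classes measures how selection acts on the mitochondrial mRNAs, so a contribution to their fall is not shown. A change in mitochondrial transcripts with PP2Ac knockdown stays open and untested.

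The breadth of change covered 7267 genes. Copy number as its whole cause is argued against, since at least 58.6% of tested genes changed on every chromosome. A local copy number or clonal difference may add to it but is not shown. The farthest window of 50 neighbouring genes, on chromosome 17 from 14945009 to 23823369, lay 0.592 below the median of all genes. In 100 shuffles of gene order the highest value was 0.497, and 46 of 10627 windows lay beyond that. Windows overlap, so these are not separate regions, and some lie on chromosomes 3 (-0.529), 5 (0.526) and 1 (-0.505). Shuffling removes every likeness of neighbouring genes, so it cannot tell copy number from other causes. Without 15 zinc finger (Zfp) genes the chromosome 17 window lay at -0.47 (bootstrap SE 0.156), against a bound of -0.5. A first count without them, among the 49 genes that end inside this window, gave -0.51. Whether co-regulated neighbours account for this window is therefore undecided. Donors of different sex stay open, as 0 of 5 sex-linked genes were present in one group and absent in the other and all were near 0. Of 10 splits of the 6 libraries 1, the real one, gave as many genes, with 0 as the highest other. These are too few splits for a share under 0.05. The sample titles name the control libraries shc and the knockdown libraries sh2. They do not say what these names stand for, how the knockdown was made or with how many constructs. All knockdown libraries share the name sh2, so effects of what it names other than through PP2Ac cannot be told apart and were not tested.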
